A study of Mus musculus with 8 samples.

How the data were processed

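RNA from microglia flow sorted from the optic nerves of mice at 3 months of age was sequenced, with 4 libraries from FF mice (floxed Nf1 alleles) and 4 from FFC mice (the same alleles and Cre under the GFAP promoter). Per the labels' protocols, tissue was dissociated, microglia were enriched on a Percoll gradient and sorted, total RNA was isolated with TRIzol and treated with DNase, and cDNA was amplified from small amounts of RNA with the Ovation method, sheared and sequenced as paired ends on an Illumina HiSeq. The labels call the libraries of a genotype biological replicates. Whether each came from 1 animal or from a pool is not given in the sources used here. The gene list test at a preset correlation, used below, compares members with other genes and takes them as nearly independent. Its p-values therefore are not a measure of the spread between libraries. The p-values for single genes and for list scores do measure the spread between these libraries. Amplification from little RNA can leave transcripts out of a library or enlarge a few of them, which widens that spread.

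The authors deposited FPKM values, fragments per kilobase of transcript scaled to the mapped fragments, as 1 table with 37447 genes and a column per library. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.4, Bowtie2 2.0.0, Cufflinks 2.0.2 and the mouse genome build mm9. They do not state the role or order of each, and the gene annotation and the settings are not given in the sources used here. FPKM values hold no read counts, so the depth behind a value is unknown and no counting interval can be given. Of the 37447 genes, 447 had a missing value in at least 1 library (331 in all 8) and were left out. A value of 0 can be a failed estimate: 20 of 2709 abundant protein-coding genes (median of at least 20 FPKM) were at 0 in some library, and 32 of 37 mitochondrial genes were at 0 in all, so such genes are given by library and said to be listed at 0. Positions are those of the deposited table. Its starts count from 0, since 21680 genes then have the same length as in GENCODE M21 and 420 otherwise, and they are printed counted from 1. GENCODE M21 gave gene types only, by Ensembl identifier, for 32797 genes (87.6%), and none of its coordinates were used. No pair of libraries had identical values.

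Values were used as deposited, as log2(FPKM + 1), for the 17753 genes with a mean of at least 1 FPKM. A fold on this scale understates the change of low genes. Genotype was tested with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes with a trend, two-sided, Benjamini-Hochberg adjustment, threshold 0.05), sex with genotype as a covariate, and the interaction with both terms. There were 32 gene lists, and those with at least 5 tested members (28) were tested with limma's camera at a preset correlation of 0.01 and adjusted over the 28. Camera with an estimated correlation and fry were alternatives, and statmod 1.5.0 served the blocked fits. Single values and list scores were compared with exact two-sided permutation tests over the 70 arrangements of 4 and 4 libraries, whose smallest p is 0.0286. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

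The groups, tests, gene lists, most other settings and the rule for named genes were fixed before the data were examined. The rule named Nf1, Gfap, Csf1r and Ccl5. It also named, in each direction, 10 genes without overlap between the genotypes, filled by the smallest unadjusted p among genes with a mean of at least 5 FPKM where too few passed, leaving out symbols of predicted genes, microRNAs, small nucleolar RNAs and pseudogenes. From each list it named up to 4 members with the smallest unadjusted p. In the text lists that were called have up to 4 such members and the others up to 2. The other settings fixed then were pseudocounts of 0.1 and 5, no expression filter or a mean of at least 5 FPKM, upper-quartile, quantile and equal-sum scaling, robust variances, array weights, summed symbols, sex, month or replicate number as a term, and leaving out each library. Added after seeing the data were leaving out FF 2 and FF 4, protein-coding genes only and the chemosensory receptor share as a covariate.

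The tests were checked on simulated data with the means and spread of these 17753 genes. The changed genes, 50 per size of change, were drawn from genes with a mean log2(FPKM + 1) of at least 3. Recovery of lower genes was not tested. Of genes changed between genotypes by a log2 of 1, 2, 4 or 6, limma recovered 0.2%, 1.7%, 45.9% and 81.5% over 20 runs, with 3 false calls per run. Between the sexes it recovered 0.1%, 1.9%, 41.5% and 74.4%. A list of 25 genes shifted by a log2 of 1 was called in 18 of 20 runs with the preset correlation and in 12 of 20 with the estimated one. The simulated genes varied independently of each other. In the data the estimated correlation between members ranged from -0.0554 (NK cell markers) to 0.875 (cytosolic ribosomal proteins). It was 0.154 for interferon-stimulated genes and 0.438 for antigen presentation. The simulation therefore does not cover lists whose members vary together.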

Results

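Microglia, the resident macrophages of the central nervous system, were flow sorted from the optic nerves of 3-month-old C57BL/6 mice, and their RNA was sequenced. FF mice carry floxed Nf1 alleles and served as controls. FFC mice carry the same alleles together with Cre recombinase under the GFAP promoter, which deletes Nf1 in astrocytes and not in the sorted microglia. There were 4 libraries per genotype, 2 from females and 2 from males. The comparison of interest was which microglial genes differ when the surrounding astrocytes lack Nf1. The deposited table gave 1 FPKM value per gene and library, with no read counts, so the depth of each library is unknown. The summed FPKM lay between 370977 (FF 4) and 704266 (FF 1), and 12046 to 14220 genes per library were above 1 FPKM. The libraries resembled each other only loosely: pairwise Spearman correlations over the 17753 tested genes ranged from 0.375 to 0.659. FF 2 and FF 4 had the lowest median correlation with the other libraries (0.398 and 0.464). FFC 4 stood apart in another way, with 90.5% of its FPKM in protein-coding genes against 58.7% to 72.8% in the others. FF 2 and FF 4 also held the largest share of FPKM in olfactory and vomeronasal receptor genes (4.20% and 3.47%), against 0.701% to 1.61% in the other 6. The share did not separate the genotypes (exact two-sided permutation p = 0.0571, adjusted p = 0.171 over 9 library measures). Another 321 genes of families usually silent in microglia, such as keratin-associated proteins and defensins, held 0.381% to 1.22% of FPKM in FF and 0.140% to 0.332% in FFC, without overlap (exact two-sided permutation p = 0.0286, adjusted p = 0.171).

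Nf1, the gene made deletable in these mice (ENSMUSG00000020716, chromosome 11, 79153195 to 79395114 in mm9), had 27.4, 60.8, 65.2 and 25.5 FPKM in FF 1 to FF 4 and 56.2, 47.8, 47.7 and 98.3 in FFC 1 to FFC 4 (limma adjusted p = 0.802). The deletion lies in astrocytes and not in the sorted cells, so these values check no label. Csf1r, the receptor that microglia need to survive, had 674 ± 274 FPKM in FF and 875 ± 194 in FFC (SD, n = 4 here and in all such values below; limma adjusted p = 0.775), and its log2 difference of 0.44 turned to -0.03 without FF 2 and FF 4. Gfap, the astrocyte gene whose promoter drives Cre, had 0.0439, 0, 0.304 and 1.03 FPKM in FF, where FF 2 is listed at 0, and 0.310, 0.0804, 0.0841 and 0.0778 in FFC.

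Genes induced by interferon and genes of antigen presentation rose as groups in FFC microglia, while no single gene passed the test. Of 27 measured interferon-stimulated genes, 26 had a higher mean in FFC, with a median difference of 1.10 on the log2(FPKM + 1) scale (camera, adjusted p = 3.0e-06; adjusted p = 0.475 with an estimated correlation). Of 20 antigen presentation genes, 19 were higher, with a median of 1.35 (adjusted p = 1.3e-05; adjusted p = 0.475 with an estimated correlation). The mean score of the interferon-stimulated genes lay between 2.84 and 3.98 in the 4 FF libraries and between 4.43 and 5.26 in the 4 FFC libraries, without overlap (exact two-sided permutation p = 0.0286, the smallest that 4 against 4 libraries can give). That p is not adjusted over the lists. The glycolysis score did not overlap either (3.76 to 4.46 in FF, 4.70 to 4.90 in FFC). Nor did the oligodendrocyte precursor score, in the other direction (1.23 to 2.63 in FF, 0.487 to 0.809 in FFC). The antigen presentation score overlapped, at 5.93 to 7.39 in FF and 7.27 to 8.46 in FFC (exact two-sided permutation p = 0.0571). Marker genes of resting microglia did not separate the genotypes: 15 of 20 were higher in FFC, with a median of 0.38 (adjusted p = 0.601) that was 0.17 without FF 2, 0.59 without FFC 1 and 0.11 without FFC 4.

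**Figure D1:**
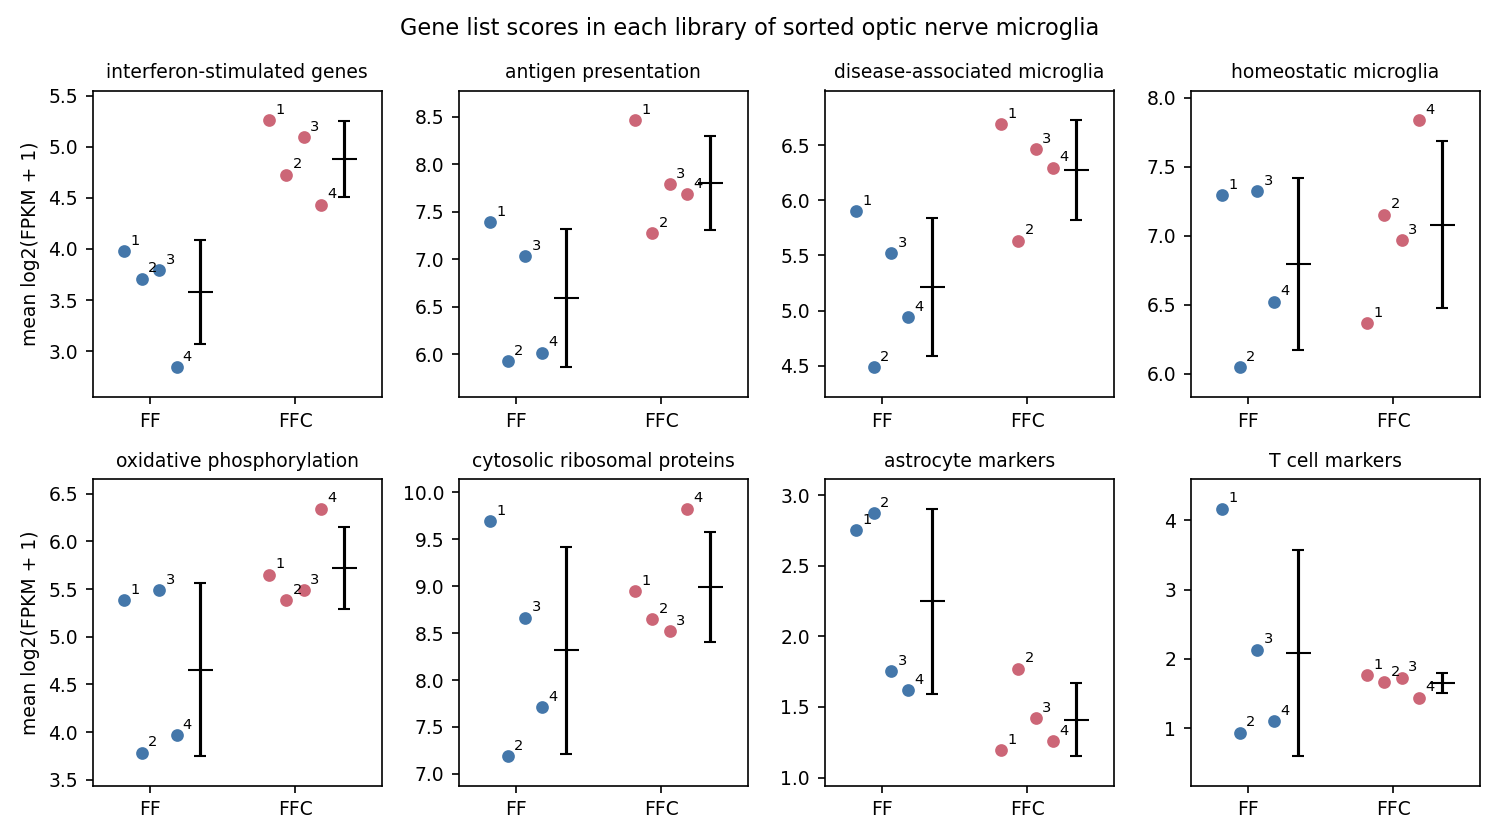
Scores of 8 gene lists in each library, as the mean log2(FPKM + 1) over the measured members. Points are libraries, numbered by replicate (n = 4 per genotype), and the black bars give the mean and SD; each panel has its own axis, which does not start at 0. The 4 FFC libraries lie above the 4 FF libraries for the interferon-stimulated genes (4.43 to 5.26 against 2.84 to 3.98), and FF 2 and FF 4 are the lowest libraries for oxidative phosphorylation and ribosomal proteins.

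Within the interferon list, the guanylate-binding GTPase Gbp2 (ENSMUSG00000028270, chromosome 3, 142283566 to 142300972) had 2.61 ± 1.53 FPKM in FF and 31.3 ± 25.1 in FFC. Rtp4 had 11.1 ± 12 FPKM in FF and 54.8 ± 19.3 in FFC. The RNA sensor Ifih1 had 5.53 ± 5.36 and 28.9 ± 16.0, and Ifi44 had 1.52 ± 1.02 and 11.3 ± 6.76. In the antigen presentation list, the class II genes H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34400154 to 34406363) and H2-Eb1 had 690 ± 409 and 590 ± 295 FPKM in FF, and 2179 ± 806 and 1764 ± 680 FPKM in FFC. The class II invariant chain Cd74 had 1932 ± 774 FPKM in FF and 5252 ± 2443 in FFC. The class I gene H2-K1 had 976 ± 628 and 2558 ± 763. Class I genes are near-identical copies of each other, so the split of reads between them is uncertain. Adjusted over the list alone, 4 of the 20 antigen presentation genes passed (H2-Ab1, H2-Eb1, H2-K1 and Cd74), against 0 over all genes. For the interferon list both counts were 0. Without FF 2 and FF 4, an alternative chosen after the data were seen, the medians were 0.83 and 0.79, and both lists passed (adjusted p = 2.9e-05 and 0.00756). With an estimated correlation no list was called in that setting (smallest adjusted p = 0.593 with an estimated correlation).

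Ccl5 (ENSMUSG00000035042, chromosome 11, 83339280 to 83344020), the chemokine this model is known for, overlapped between the genotypes and did not pass the test. Its FPKM was 88.0, 0.721, 9.95 and 0 in FF 1 to FF 4, and 611, 59.9, 93.9 and 1.74 in FFC 1 to FFC 4. The difference of mean log2(FPKM + 1) was 3.12, with an exact two-sided permutation p of 0.171 and a limma adjusted p of 0.759. The value of Ccl5 between FFC and FF was 1.97 without FFC 1, 0.84 without FF 2 and FF 4 and 5.17 with month as a covariate, none of which passed. Among the 24 measured chemokines, the macrophage chemokine Ccl4 had 1.87, 0.697, 11.3 and 0 FPKM in FF and 57.1, 27.1, 87.3 and 46.9 in FFC. Ccl6 had 9.26 ± 10.3 FPKM in FF and 75.9 ± 34.7 in FFC. Adjusted over the list alone, 3 chemokines passed, Ccl4, Ccl6 and Cxcl9 (the last named after its values were seen), and 0 passed over all genes. The chemokine list was not called, with 13 members higher and 11 lower (median 0.61, and 0.34 without FF 2 or FF 4; adjusted p = 0.0996, 0.0387 without FF 3 and 0.658 with an estimated correlation), and neither were, with 0 members passing adjusted over the list alone, the inflammatory cytokines and NF-kB targets (17 of 19 higher, median 0.46, adjusted p = 0.106; 0.00899 without the expression filter, 0.0494 without FFC 4 and 0.658 with an estimated correlation). The median of the inflammatory cytokines and NF-kB targets was 0.71 without FF 1 (camera adjusted p = 0.0994). In that list, Il1a had 17.8 ± 6.18 FPKM in FF and 51.3 ± 6.54 in FFC, and Tnf had 0.999, 0, 6.87 and 1.12 in FF and 12.5, 17.0, 16.9 and 12.1 in FFC.

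**Figure D2:**
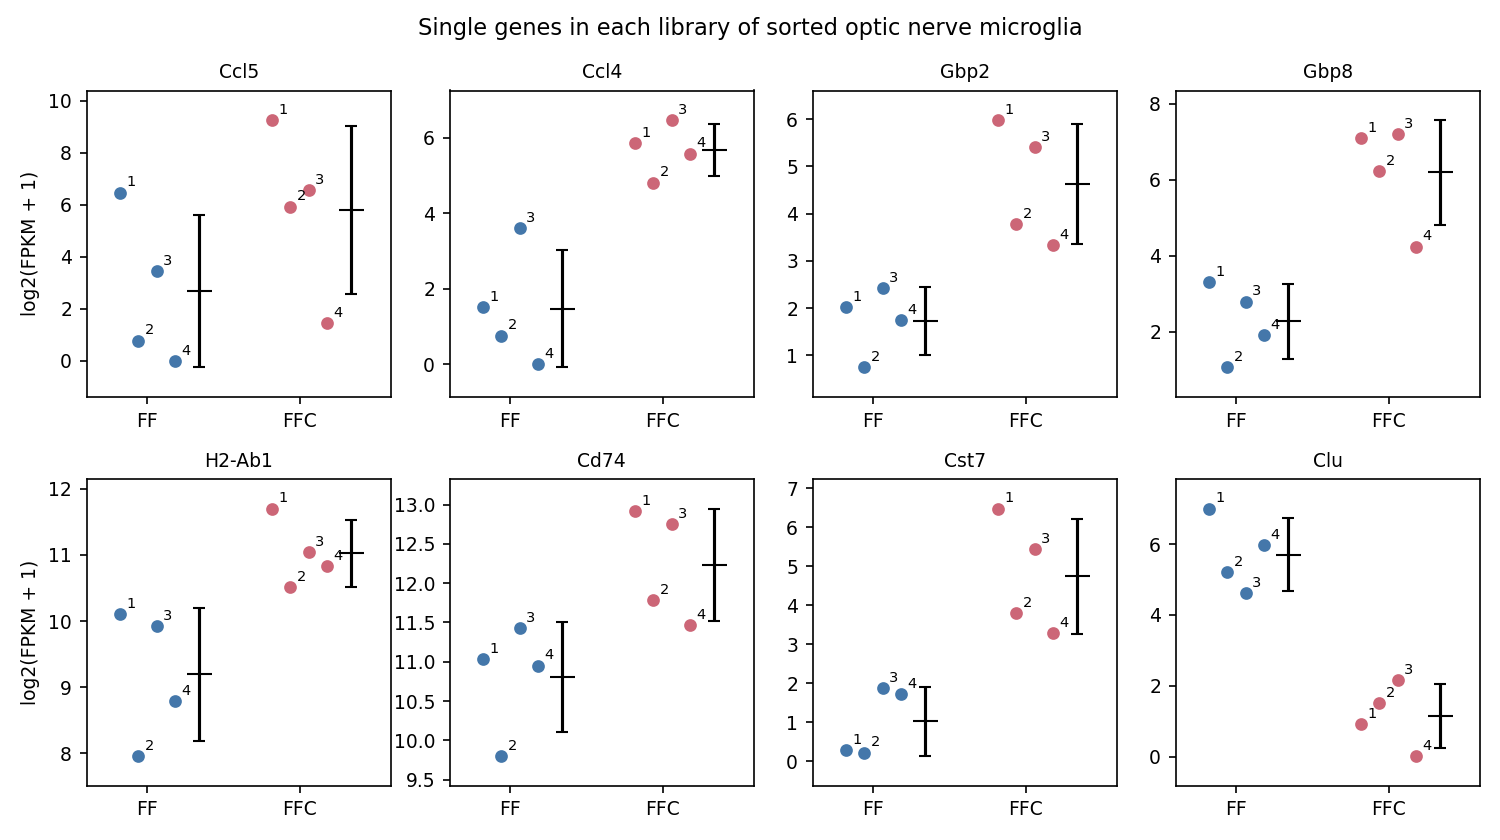
Expression of 8 named genes in each library, as log2(FPKM + 1). Points are libraries, numbered by replicate (n = 4 per genotype), and the black bars give the mean and SD of the log values; each panel has its own axis. Ccl5 overlaps between the genotypes, whereas Ccl4, Gbp2, Gbp8, H2-Ab1, Cd74 and Cst7 lie higher in every FFC library than in every FF library and Clu lies lower; none of the 8 passed the test over all genes.

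The disease-associated microglia list, genes that microglia induce around damage and plaques, rose in FFC, with 22 of 25 members higher and a median of 0.81 (adjusted p = 0.000497; adjusted p = 0.475 with an estimated correlation). The cystatin Cst7 had 1.34 ± 1.33 FPKM in FF and 37.9 ± 36.5 in FFC, and was the 1 member that passed when adjusted over the list alone. Timp2 had 43.5 ± 28 and 146 ± 70.5 FPKM. The lysosomal protein Cd68 had 322 ± 139 and 733 ± 208, and the integrin Itgax 11.1 ± 9.0 and 39.4 ± 21.5. The complement and phagocytosis list also rose (19 of 21 higher, median 0.70, adjusted p = 0.0176; adjusted p = 0.658 with an estimated correlation), with 0 members passing over all genes or adjusted over the list alone. There C1qa had 287 ± 278 FPKM in FF and 640 ± 255 in FFC, C1qc had 302 ± 185 and 647 ± 46.8, and C4b had 29.1 ± 24.3 and 89.8 ± 43.2. Without FF 2 and FF 4 neither list was called (medians 0.19 and 0.17, adjusted p = 0.161 and 0.547), and the complement call was also lost without FF 2 alone (median 0.46, adjusted p = 0.0956) or FFC 1 alone (median 0.70, adjusted p = 0.0561) and with a pseudocount of 0.1 (median 0.71, adjusted p = 0.0566). With the chemosensory share of each library as a covariate the medians of both lists were 0.03 and -0.04 (adjusted p = 0.268 and 0.873), and the resting microglia list was called lower (median -0.66, adjusted p = 0.0233). Without that covariate the resting microglia list had a camera adjusted p of 0.887 with an estimated correlation. Among resting microglia genes, Tmem119 had 231 ± 110 FPKM in FF and 374 ± 108 in FFC, and Cx3cr1 had 57.2 ± 26.6 and 92.1 ± 10.5.

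Housekeeping groups rose with these lists. Oxidative phosphorylation genes were higher in 32 of 34 cases (median 1.00, adjusted p = 3.6e-05; adjusted p = 0.607 with an estimated correlation), cytosolic ribosomal proteins in 35 of 35 (median 0.66, adjusted p = 0.0147; adjusted p = 0.777 with an estimated correlation) and glycolytic genes in 14 of 16 (median 0.59, adjusted p = 0.0462; adjusted p = 0.475 with an estimated correlation). Immediate-early genes, which tissue dissociation also induces, were higher in 18 of 20 cases (median 1.28, adjusted p = 0.000149; adjusted p = 0.658 with an estimated correlation). In none of these 4 lists did a member pass, over all genes or adjusted over the list alone. The ATP synthase subunit Atp5d had 18.4 ± 12.4 FPKM in FF and 104 ± 45.9 in FFC. Uqcrc1 had 7.52 ± 5.38 and 34.2 ± 14.1, Uqcrh 51.6 ± 47.2 and 122 ± 30.7, and Ndufa9 32.4 ± 20.1 and 96.8 ± 63.9. Rpl35 had 82.7 ± 98.0 and 202 ± 144 FPKM, Rpl8 214 ± 128 and 467 ± 333, and Gapdh 712 ± 439 and 1785 ± 415. Zfp36 had 29.4 ± 22.7 and 127 ± 62.3, Junb 14.2 ± 20.0 and 75.3 ± 51.6, and Egr1 37.5 ± 44.1 and 145 ± 66.3. Without FF 2 and FF 4, the libraries with the highest chemosensory receptor share, none of the 4 lists was called (adjusted p = 0.209 for each); the medians were 0.24, -0.21, 0.48 and 0.66 in the order given. With the chemosensory share as a covariate the medians were -0.12, -0.64, 0.44 and -0.11, and the ribosomal list was called lower (adjusted p = 0.0147). The ribosomal call was also lost without FF 2 (median 0.23, adjusted p = 0.351), FF 4 (0.39, 0.0998) or FFC 4 (0.40, 0.214) alone, and its median was 1.09 without FF 1. The glycolysis call was lost without FF 2 (adjusted p = 0.0764), FF 4 (0.0849), FFC 1 (0.0840) or FFC 2 (0.0527) alone, at medians of 0.61, 0.60, 0.63 and 0.67, and the median was 0.94 without FF 1. With a pseudocount of 0.1 the ribosomal and glycolysis lists had adjusted p of 0.0531 and 0.0835 (medians 0.66 and 0.75), and glycolysis had 0.0529 after quantile normalization (median 0.42) and 0.0807 among protein-coding genes (median 0.59). The immediate-early median was 0.81 without FF 2 and 0.76 without FFC 4, with the call kept.

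Markers of several cell types outside the sort fell in FFC. Astrocyte markers were lower in 8 of 11 measured cases (median -0.55, adjusted p = 0.0176; adjusted p = 0.475 with an estimated correlation), mural and fibroblast markers in 7 of 8 (median -0.87, adjusted p = 0.0195; adjusted p = 0.475 with an estimated correlation) and erythroid markers in 5 of 6 (median -1.07, adjusted p = 0.0195; adjusted p = 0.475 with an estimated correlation). The secreted chaperone clusterin, Clu (ENSMUSG00000022037, chromosome 14, 66587320 to 66600385), had 62.2 ± 46.2 FPKM in FF and 1.55 ± 1.47 in FFC, and was the 1 astrocyte marker that passed when adjusted over the list alone. Of mural or erythroid markers 0 did, and 0 members of the 3 lists passed over all genes. Atp1b2 had 14.1 ± 23.6 FPKM in FF and 0.953 ± 1.13 in FFC. The collagen gene Col1a2 had 4.39 ± 4.01 and 1.00 ± 1.22, and the erythroid heme enzyme Alas2 had 4.85 ± 7.08 and 0.177 ± 0.132. Hba-a1 had 25.4 ± 9.32 and 12.6 ± 6.22 FPKM and Hba-a2 23.9 ± 18.8 and 9.19 ± 4.72, and as near-identical copies these share reads. The astrocyte call was lost without FF 1 (median -0.43, adjusted p = 0.0749) or FF 2 (-0.35, 0.123), the mural call without FF 1 (-1.01, 0.0663) or FF 2 (-0.70, 0.0956), and the erythroid call without FF 1 (-0.68, 0.0994). The astrocyte median was -0.90 without FFC 2 and -0.32 without FFC 4, with the call kept. With a pseudocount of 0.1 the astrocyte and mural medians were -1.28 and -1.52, and the mural call was lost (adjusted p = 0.0531). Without FF 2 and FF 4 together, erythroid markers (median -1.48, adjusted p = 0.0103) and T cell markers (median -1.56, adjusted p = 0.00284) were called lower, though neither was with an estimated correlation (smallest adjusted p of any list = 0.593). Astrocyte and mural markers were not called there (adjusted p = 0.158 for each), with medians of -0.50 and -0.87.

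**Figure D3:**
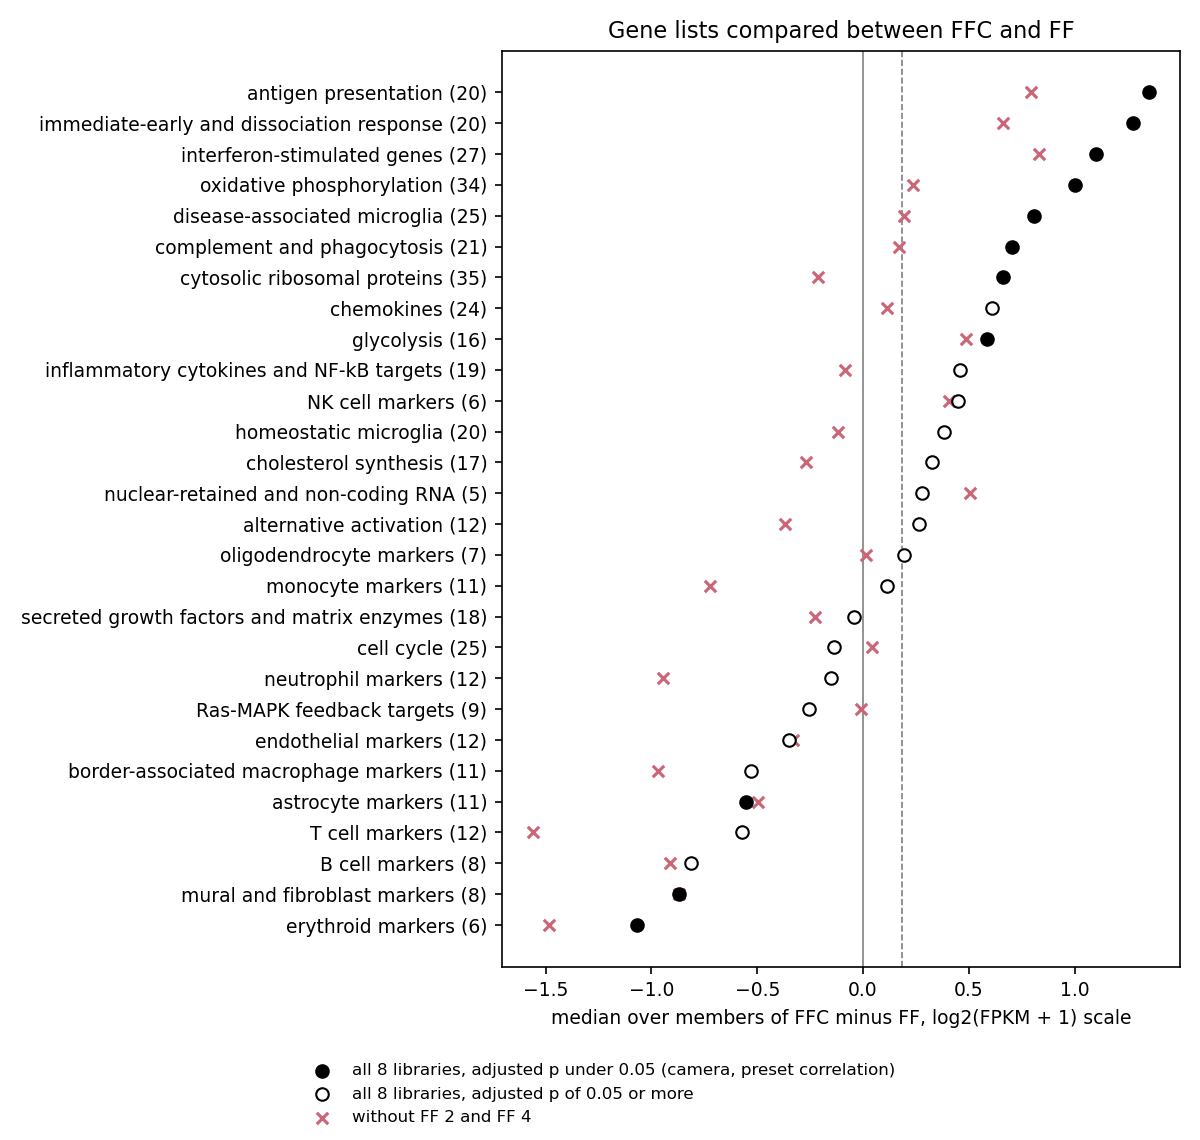
Median difference between FFC and FF over the measured members of each of the 28 tested gene lists, in log2(FPKM + 1), with the number of members in parentheses. Filled circles passed the test in all 8 libraries, open circles did not, crosses give the medians without FF 2 and FF 4, and the dashed line marks the median of all tested genes (0.19). Interferon-stimulated genes and antigen presentation keep medians of 0.83 and 0.79 without these libraries, while the ribosomal protein median crosses 0 to -0.21.

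Over all 17753 tested genes, limma called 0 between FFC and FF (smallest adjusted p = 0.382). At an unadjusted p under 0.05 there were 1146 genes, 802 higher and 344 lower in FFC, where 888 would pass by chance. The share of higher genes was 70.0% here, 59.7% of the 1089 genes at that threshold after upper-quartile scaling and 39.8% of the 998 without FF 2 and FF 4. All values of 542 genes (3.05%) were higher in FFC than in FF and those of 229 (1.29%) were lower, against 1.43% expected by chance in each direction. Leaving out FF 1 or FFC 4 gave 1 called gene each, the microRNA gene Mir15a (adjusted p = 0.000155) and the small nucleolar RNA SNORA65 (adjusted p = 0.00177), both named after their values were seen. The median difference of all genes was 0.19, and 0.03 after quantile or upper-quartile scaling. Relative to it, the interferon and antigen presentation medians were 0.91 and 1.17. Those of oxidative phosphorylation, immediate-early genes and disease-associated microglia were 0.81, 1.09 and 0.62, and those of ribosomal proteins, complement and glycolysis 0.48, 0.52 and 0.40. The astrocyte, mural and erythroid medians were -0.74, -1.05 and -1.25 relative to it.

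The genes with the smallest unadjusted p among those without overlap did not pass, and they are given by their values. The acute-phase protein gene Saa3 (ENSMUSG00000040026, chromosome 7, 53967368 to 53971046) had 0.401, 0, 0 and 0 FPKM in FF and 25, 8.70, 32.4 and 97.5 in FFC (limma adjusted p = 0.382). Gbp8 (ENSMUSG00000034438, chromosome 5, 105443172 to 105482580), another guanylate-binding GTPase, had 4.67 ± 3.48 FPKM in FF and 93.9 ± 60.2 in FFC, with a log2 difference of 3.93 ± 0.83 (SE; adjusted p = 0.496). The apolipoprotein gene Apoc1 had 7.11, 1.70, 0 and 6.41 in FF and 236, 53.7, 31.0 and 42.1 in FFC. Afmid, an enzyme of tryptophan breakdown, had 0.151 ± 0.0998 FPKM in FF and 17.8 ± 7.76 in FFC. Tppp had 0.984 ± 0.706 and 28.9 ± 16.9, Dpm2 2.61 ± 2.09 and 39.3 ± 23.5, and Pgap2 3.51 ± 3.42 and 59.3 ± 48.8. The minor spliceosome RNAs U11 and U12 had 0 in 3 of 4 FF libraries each and 29.1 (FF 3) and 13.2 (FF 4) in the fourth. In FFC they had 72.9, 87.5, 87.6 and 424, and 131, 50.3, 17.0 and 163.

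In the other direction, Clu (log2 difference -4.55 ± 0.80, SE; adjusted p = 0.382) was joined by Rab34, a small GTPase of cilium formation, at 38.2 ± 27.1 FPKM in FF and 0.948 ± 0.984 in FFC. The other 8 genes with the smallest p were immunoglobulin variable segments or chemosensory receptors, large families whose more similar members can share reads. Igkv17-127 had 376, 62.5, 674 and 12.4 FPKM in FF and 0, 0, 3.06 and 0 in FFC. Igkv10-96 had 6047, 37.7, 63.7 and 68.5 against 0, 17.6, 0.709 and 0. Ighv1-80 had 454, 156, 96.4 and 215 in FF and 11.7, 0, 30.8 and 0 in FFC. Ighv1-55 had 9.99, 42.9, 707 and 1390 against 0, 7.71, 0.698 and 0. Ighv1-67 had 78.9, 814, 255 and 112 against 0, 10.9, 54.1 and 0. The olfactory receptor Olfr692 had 126, 133, 181 and 15.9 in FF and 3.27, 7.48, 0.0340 and 0 in FFC. Olfr282 had 13.7, 200, 7.91 and 33.4 against 0, 1.61, 0 and 0, and the vomeronasal receptor Vmn1r112 had 50.7 ± 40.9 and 3.34 ± 3.71.

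The remaining lists were not called between the genotypes. Their adjusted p were 0.0852 for T cell markers, 0.118 for endothelial markers, 0.244 for border-associated macrophages, 0.356 for B cells, 0.381 for neutrophils, and 0.518 for the cell cycle. They were 0.665 for both NK cell and monocyte markers, 0.696 for nuclear-retained and non-coding RNA, 0.794 for alternative activation, 0.830 for Ras-MAPK feedback targets, 0.879 for both oligodendrocyte markers and secreted growth factors and matrix enzymes, and 0.914 for cholesterol synthesis. The median differed in sign from the test for monocyte markers, alternative activation and oligodendrocyte markers, and the mean did for alternative activation, oligodendrocyte markers and secreted growth factors. T cell markers were called lower without FF 2 (adjusted p = 0.0164) or FF 4 (0.0259) and among protein-coding genes (0.0392), endothelial markers without FFC 1 (0.0395) and border-associated macrophage markers without FFC 4 (0.0292). These medians moved with single libraries. That of T cell markers was -0.57, and 0.12 without FF 1 (adjusted p = 0.752), whose score of 4.17 compares with 0.94 to 2.13 in the other FF libraries. The T cell median was -0.88 without FF 2, -0.92 without FF 4 and -0.87 without FFC 2. The endothelial median of -0.35 was -0.06 without FF 2 (adjusted p = 0.243), -0.64 without FF 4, -0.75 without FFC 1 and -0.19 without FFC 2. The border-associated macrophage median of -0.53 was -0.20 without FFC 3 (adjusted p = 0.816), -0.24 without FF 1, -0.92 without FF 2 and -0.88 without FFC 4. With the chemosensory share as a covariate, T cell markers (median -1.56, adjusted p = 0.00637), border-associated macrophage markers (median -1.62, adjusted p = 0.0166) and cholesterol synthesis (median -1.08 from 0.32, adjusted p = 0.0161) were called lower. With an estimated correlation and all 8 libraries the T cell, endothelial, border-associated macrophage and cholesterol lists had adjusted p of 0.658, 0.475, 0.777 and 0.963. Neuron, oligodendrocyte precursor, photoreceptor and Schwann cell markers had fewer than 5 members that met the expression filter and were tested only without it, on 18, 13, 12 and 7 genes. Oligodendrocyte precursor markers were then called lower (median -0.47, adjusted p = 0.0288), and the others were not called (adjusted p = 0.0823, 0.141 and 0.639). In the T cell list the kinase Lck had 34.9 ± 30.6 FPKM in FF and 2.72 ± 2.55 in FFC and passed when adjusted over the list alone. In the other lists tested here 0 members did. Among border-associated macrophage genes, Stab1 had 484 ± 195 FPKM in FF and 169 ± 139 in FFC, and Mrc1 had 189 ± 91.4 and 89.9 ± 58.0; the monocyte gene Ace had 9.25 ± 4.78 and 1.30 ± 1.74.

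Between male and female mice, the sex-linked genes followed the labels and no gene passed the test. The Y-linked translation factor gene Eif2s3y (ENSMUSG00000069049) had 17.2 to 113 FPKM in the 4 male libraries and 0 to 1.92 in the 4 female ones, and Uty had 9.67 to 53.4 against 0 to 0.203. Kdm5d had 2.77 to 20.5 against 0 to 0.219, and Xist, the RNA that silences an X chromosome in females, had 0.0940 to 0.205 in males and 1.07 to 14.6 in females (exact two-sided permutation p = 0.0286 for each of these 4). Ddx3y, also on the Y chromosome, overlapped, since FF 1, labelled female, had 8.89 FPKM against 3.83 to 10.3 in males (exact two-sided permutation p = 0.114). With genotype as a covariate, limma called 0 genes (smallest adjusted p = 0.152, for the immunoglobulin segment Ighv1-54, named after its values were seen) and 709 had an unadjusted p under 0.05. The number called was 2 without FF 2 and 3 without FF 4, all of them unnamed genomic clone loci.

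The interaction between genotype and sex, resting on 2 libraries per combination, was called for 0 genes by limma (smallest adjusted p = 0.104), and 567 had an unadjusted p under 0.05. Its median standard error was 1.77 on the log2 scale, so differences between the sexes in the effect of genotype are not ruled out. Among named protein-coding genes the neutrophil gene S100a9 had the smallest unadjusted p (0.000221, adjusted p = 0.785), with 1126, 83.2, 64.3 and 130 FPKM in FF and 2.25, 156, 248 and 2.58 in FFC, where FFC 2 and FFC 3 are the males. Without FF 1 or without FFC 4 the count was 1, an unnamed genomic clone locus each time.

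The dates in the sample titles put 3 FF libraries and 1 FFC library in November and 1 FF library and 3 FFC libraries in December, so month and genotype are largely tied. Within November the medians were 1.32 for interferon-stimulated genes, 1.49 for antigen presentation, 0.91 for oxidative phosphorylation, 0.35 for ribosomal proteins, 0.96 for disease-associated microglia and -0.42 for immediate-early genes. Within December the medians of the same lists were 1.89, 1.77, 1.75, 1.32, 1.32 and 2.47. Astrocyte and mural markers had medians of -1.02 and -1.70 in November and 0.66 and 0.48 in December, and erythroid markers -1.10 and -0.78. With month as a covariate, 8 lists were called and limma called 0 genes. The immediate-early median fell from 1.28 to 0.75 (adjusted p = 0.0200). The astrocyte, mural, erythroid and glycolysis calls were then lost (adjusted p = 0.0998, 0.0998, 0.0608 and 0.0608) at medians of -0.55, -0.98, -0.99 and 1.04, and the chemokines were called (median 1.42, adjusted p = 0.00761; without month, adjusted p = 0.658 with an estimated correlation).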

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

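The tests that leave out FF 2 and FF 4 or another pair of FF libraries, use marker scores, the chemosensory share, Igkc or gene families, or count other splits of the libraries were chosen only after the result was seen; month as a covariate, single libraries left out, the estimated correlation and fry were planned, and month was set against these explanations only afterwards. Of 222 groups of 4 values examined, 19 held a library far from the other 3, where a rate of 5% gives 11.1. In several of the 19, such as Saa3 in FF 1 and Esam in FFC 2, the other 3 values were 0. Any value above 0 is then flagged, so the excess over 11.1 decides nothing.

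The interferon-stimulated and antigen presentation lists were higher in FFC among 11 lists called with the preset correlation. Of the 35 splits of the libraries into 4 and 4, 1 gave that number, the real one (highest other 9). This count covers all lists and was chosen after the result was seen, so it does not exclude chance for the lists named here. The split that puts FFC 4 with FF 2, FF 3 and FF 4 gave the interferon list an unadjusted camera p of 1.2e-06, against 1.1e-07 in the real one. With an estimated correlation or with fry 0 lists were called. More background or fewer microglial transcripts in FF 2 and FF 4 is argued against as the whole cause with the preset correlation. Without both libraries the larger camera adjusted p of both lists was 0.00756. With an estimated correlation the smallest camera adjusted p of any list there was 0.593. The medians fell from 1.10 and 1.35 to 0.83 and 0.79, with a lower quartile of 0.19 for antigen presentation. Any other pair of FF libraries left out gave medians of 0.87 to 1.58 and 1.22 to 1.95. Part of the difference, more so for antigen presentation, therefore rests on FF 2 and FF 4. Background in all FF libraries is argued against only as far as the chemosensory share measures it. With that share as a covariate the medians were 1.37 and 0.81 (larger camera adjusted p = 0.0314), while the ribosomal median turned to -0.64. The share of the other 321 usually silent genes, which was higher in every FF library than in every FFC library, was not used as a covariate. Background of that kind stays open. The month in the sample titles is not decided. With month as a covariate the larger camera adjusted p was 1.9e-07 at the preset correlation, which is not a measure of the spread between libraries. A month fit with an estimated correlation was not run. Both medians were positive within each month. That and the fit rest on FFC 1, the highest library for both scores, in November. In December they rest on FF 4, the lowest for the interferon score. What the dates mark is not given in the sources used here. T and B cells in the FFC sorts are argued against only by a score of 24 T, B and NK cell markers that leaves out Ccl5. Ccl5, in the T and NK cell lists, was itself higher in FFC (log2 difference 3.12), and a score with it was not tested. The antigen presentation score minus that marker score was higher in FFC by 1.63 (exact two-sided permutation p = 0.0286). For the antigen presentation score alone the exact p was 0.0571. The marker score itself differed by -0.42 (exact p = 0.429), or -0.08 without FF 1. NK cell markers alone, Ccl5 among them, were higher for 4 of 6 (median 0.45, camera adjusted p = 0.665), so NK cells stay open. A response of microglia to Nf1-deficient astrocytes also stays open and was not tested apart from genotype, and with an estimated correlation neither list passed (adjusted p = 0.475).

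The oxidative phosphorylation and ribosomal protein lists were higher in FFC, a pattern that may come largely from FF 2 and FF 4. Without both libraries the medians were 0.24 (quartiles 0.00 to 0.69) and -0.21, from 1.00 (quartiles 0.59 to 1.49) and 0.66. Any other pair of FF libraries left out gave 1.01 to 1.63 and 0.27 to 1.63. FF 2 and FF 4 are the lowest FF libraries for both list scores, so the comparison of pairs restates that and is no separate support. Without FFC 4, the highest library for both lists, the medians were 0.67 and 0.40. The month in the sample titles is not decided. With month as a covariate the larger camera adjusted p was 0.00393 at the preset correlation, but the estimated correlations of these lists were 0.374 and 0.875. A month fit with an estimated correlation was not run. The single FF library of December is FF 4. Fewer microglial transcripts in these libraries is a candidate explanation that the deposited values cannot separate from more background, and an effect of genotype stays open.

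Variable segments of immunoglobulin genes were lower in FFC, a pattern found in the data: the Igkv family had a median of -1.34 and the Ighv family -1.01. More background in FF 2 and FF 4 is argued against as the whole cause with the preset correlation only. Without them the medians were -2.23 and -1.55, but over all libraries neither family passed with an estimated correlation (camera adjusted p = 0.692). FF 1 and FF 3 then remain, and FF 1 held 10.7% of its FPKM in immunoglobulin variable genes. The other FF libraries held 1.59% to 3.83%, and how far the medians rest on FF 1 was not tested. This share overlapped between the genotypes, at 1.59% to 10.7% in FF and 0.472% to 6.46% in FFC (exact two-sided permutation p = 0.514). Fewer antibody-producing cells in the FFC sorts stays open, as the kappa constant gene Igkc did not decide it (log2 difference -0.66, exact two-sided permutation p = 0.6). Reads shared between near-identical segments and background in all FF libraries were not tested as explanations.

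For single genes, 35 of 35 splits between the genotypes gave at least as many calls as the real one (0, highest other 4), and for sex 34 of 34 did (0, highest other 3); with a real count of 0 no split can give fewer, so these comparisons decide nothing about chance. At an unadjusted p under 0.05, 3 of 35 splits gave at least 1146 genes, the highest other 1252.

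The following values stood far from the other 3 libraries of their genotype. In FF 1, Igkc had 42819 FPKM against 1214 to 8215, Igkv10-96 had 6047 against 37.7 to 68.5, and Saa3 had 0.401 against 0. In FF 3, Egr1 had 103.5 FPKM against 12.8 to 18.2 and U11 had 29.1 against 0. In FF 4, U12 had 13.2 FPKM against 0, and Olfr692 had 15.9 against 126 to 181. In FFC 1, Tyms had 64.9 FPKM against 3.03 to 4.40 and Gfap had 0.310 against 0.0778 to 0.0841. In FFC 2, Slc4a4 had 1.19 FPKM against 0.157 to 0.208, Gjb6 had 0.668 against 0 to 0.0560, Esam had 0.492 against 0, and Olfr282 had 1.61 against 0. In FFC 3, Igkc had 36717 FPKM against 1688 to 4307, Igkv17-127 had 3.06 against 0, and Enpp2 had 1.31 against 0.00712 to 0.0732. In FFC 4, U11 had 424 FPKM against 72.9 to 87.6, Hba-a1 had 21.9 against 8.93 to 9.90, and Malat1 had 137 against 453 to 545.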

How the results depend on the processing

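The alternatives that leave out FF 2 and FF 4, keep protein-coding genes only or add the chemosensory share were chosen after the data were seen; all others were planned. The number of called lists, 11, was 13 without the expression filter, 7 with a pseudocount of 0.1, 8 with month, 8 with the chemosensory share (2 higher and 6 lower, against 8 and 3), 0 with an estimated correlation, 0 with fry and 4 without FF 2 and FF 4. It ranged from 7 (without FF 2) to 12 (without FF 3 or FFC 4) with 1 library left out. Camera with an estimated correlation allows for members that vary together, and fry does not compare a list with other genes. For the pseudocount and for the libraries left out the cause was not tested. With 1 library left out, the genes called ranged from 0 to 1 between genotypes (1 without FF 1 or FFC 4), from 0 to 3 between the sexes (2 without FF 2, 3 without FF 4) and from 0 to 1 for the interaction (1 without FF 1 or FFC 4); every other alternative called 0 genes, and the cause was not tested. With 1 library left out, the Ccl5 difference ranged from 1.97 to 4.57, and it passed in none of these fits.

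Replicate numbers did not pair the libraries: same-numbered deviations correlated at -0.04, 0.03, -0.01 and -0.05. With the replicate block 12 lists and 0 genes were called, the chemokines being the list gained (adjusted p = 0.0429). Without the block the chemokine list had a camera adjusted p of 0.658 with an estimated correlation.

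Of 209 comparisons of the 11 called lists with an alternative, 147 kept the call, 58 lost it and 4 reversed. The ribosomal list was -0.21 without FF 2 and FF 4. With the chemosensory share as a covariate, the ribosomal, immediate-early and oxidative phosphorylation lists were -0.64, -0.11 and -0.12. Of 322 comparisons of the other lists, 15 gained a call. Of 1808 comparisons of 101 named genes, 24 reversed; no gene had passed. Without FF 2 and FF 4 the differences were -0.027 for Csf1r, -0.13 for Rpl14, -0.0092 for Epha2 and 0.44 for Eno2. With the chemosensory share they were -0.35 for Csf1r, -0.055 for Rpl35, -0.14 for Rpl8, -0.052 for Rps18, -0.58 for Rpl14, -0.038 for C1qa, 0.58 for Vtn, -0.22 for Tmem119, -0.022 for Cx3cr1, -0.68 for Klrd1, -0.59 for Dusp6 and 0.92 for Eno2. With month they were -0.19 for Dusp6 and 0.31 for Thy1. With 1 library left out, Dusp6 ranged from -0.071 to 0.77, Thy1 from -0.96 to 0.47 and Rom1 from -0.87 to 0.22. The cause of these reversals was not tested. Depth is unknown, so how far it limits any call cannot be given.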

Other observations

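The gene families in this part were compared only after the data were seen, by camera over 235 families that share the start of a symbol, and none passed with an estimated correlation (adjusted p = 0.692 for each family named here). The guanylate-binding proteins, interferon-induced GTPases that act against intracellular microbes, were higher in FFC for 10 of 10 measured members, with a median of 1.70 (adjusted p = 8.7e-05), and 1.97 without FF 2 and FF 4 (adjusted p = 0.000493). Gbp9 had 5.63 ± 1.24 FPKM in FF and 35.5 ± 27.6 in FFC (SD, n = 4), and Gbp6 had 2.81 ± 4.56 and 25.6 ± 21. Members of the family are near-identical, so the split of reads between them is uncertain. Histone genes, most of which are transcribed while DNA is replicated, were higher for 47 of 54 members (median 1.22, adjusted p = 8.0e-05), and not called without FF 2 and FF 4 (median 0.73, adjusted p = 0.644), while the cell cycle list was not called.

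The immunoglobulin light chain segments Igkv were lower for 61 of 84 genes (median -1.34, adjusted p = 6.9e-06) and the heavy chain segments Ighv for 63 of 91 (median -1.01, adjusted p = 8.0e-05). The number of these segments above 1 FPKM was 117, 112, 100 and 63 of 216 in FF and 80, 91, 111 and 36 in FFC (exact two-sided permutation p = 0.4). Olfactory receptors were lower for 599 of 936 genes (median -0.46, adjusted p = 0.000133) and vomeronasal receptors for 188 of 296 (median -0.49, adjusted p = 0.000986), and without FF 2 and FF 4 their medians were 0.07 and 0.02 (adjusted p = 0.895 and 0.844). The directions of the 6 families named so far held with all 8 libraries under upper-quartile, quantile and equal-sum scaling. In all, 13 families were called, and the other 7 were not called without FF 2 and FF 4. Of these, the interferon alpha genes Ifna were lower for 7 of 8 members (median -1.14, adjusted p = 0.0306), against the direction of the interferon-stimulated genes. Ifna genes belong to the 321 usually silent genes whose share was higher in every FF library than in every FFC library. Their fall therefore cannot be told apart from that background. The medians were -0.90 for Pcdhb, -1.30 for Serpina, -1.17 for Rhox and -0.19 for predicted genes with Gm symbols, and 1.43 for Ndufa and 0.92 for Cox.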
